A study of Homo sapiens with 12 samples.

How the data were processed

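The data were peak lists from CUT&RUN, an assay in which an antibody brings a nuclease to its target in permeabilised cells so that DNA bound by the target is cut out and sequenced. The antibody recognised LSD1 (KDM1A), a histone demethylase, and the cells were erythroid cells grown from human CD34+ blood stem and progenitor cells. Per the labels, cells of the same 3 donors were taken at day 11 and day 14, which gave 6 LSD1 libraries, named here by day and replicate, a replicate number standing for the same donor on both days. The 6 matching IgG control libraries were not analysed here. No label gave a batch.

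The authors called the peaks separately for each library, 1 list per library, and the submitters' processing notes name MACS2, a peak caller, and the genome build GRCh38. The aligner, the use of a control in peak calling, the removal of listed problem regions and the software versions were not given in the sources used here. Each deposited list gave a chromosome, a start, an end and a score per peak. The score is a whole number of 13 or more in all 6 lists, the value that a q-value of 0.05 has when -log10 is multiplied by 10 and truncated. The score was used only to rank or filter peaks within its own list, because scores and ranks of lists from libraries of different depth are not comparable. The read depth behind each list is unknown, so a missing peak does not show missing binding.

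Lists differed in length, so the 20000 highest-scoring peaks of each library on chromosomes 1 to 22 and X were compared, with peaks of equal score in a seeded random order. The gene table was that of NCBI RefSeq for the same build, with 19974 protein-coding genes on those chromosomes. The table used gives the start and end of a gene but neither its strand nor its exons, and no genome sequence was used. The planned distance to the transcription start was therefore replaced by the distance to either annotated end of a protein-coding gene. A peak lay at a gene end when its midpoint was within 1 kb of such an end. This window holds transcription starts and transcript ends alike, and a peak between neighbouring genes counted for both. A transcription start inside the outer bounds of a gene is missed, so a peak called intragenic can lie at such a start. Exons, introns and untranslated regions were not told apart. Planned comparisons of sequence motifs and a match on CpG content were not run.

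A region was reproducible when merged top peaks of all 3 donors of a day overlapped by at least 1 bp, and a gene had a reproducible gene-end peak when the same end had a top peak in all 3 donors. Backgrounds came from 100 circular shifts of the peaks within their chromosomes. Overlap of libraries was the Jaccard index, the bases covered by both lists over the bases covered by either. A gene was specific to a day when the same end had a top peak in 3 of 3 donors and neither end had one in any donor of the other day. Days were compared by two-sided exact permutation tests over libraries, whose smallest p with 3 against 3 is 0.1. The donor labels pair the libraries across days, and the paired sign-flip permutation test can give no p below 0.25. Calls made per gene cannot pass a test with 3 libraries per day, so the number of day-specific genes was set against the 10 splits of the 6 libraries.

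The 17 gene lists were fixed before the data were examined, as were the tests. They were the COPII coat and ER export, LSD1 corepressor complexes, erythroid transcription factors, globins with their chaperone, haem synthesis and iron, and red cell membrane and blood groups. Others were erythroid maturation and survival, congenital dyserythropoietic anaemia genes, the unfolded protein and integrated stress response, cell cycle and cytokinesis, ribosomal proteins, and olfactory receptors as genes that blood cells do not use. The rest were markers of stem and progenitor cells, megakaryocytes, neutrophils and monocytes, mast cells with basophils and eosinophils, and lymphoid cells. At gene ends, list members were compared with all other protein-coding genes by two-sided Fisher's exact tests. Over gene bodies with 10 kb on both sides, they were compared with 10000 random lists matched on gene length in 20 bins. Each family of 34 tests, 17 lists on 2 days, was adjusted by the Benjamini-Hochberg method. Log2 odds ratios had 0.5 added to each count. Neighbouring genes share peaks, so genes are not independent and these p values are approximate.

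The genes named were fixed by rule. They were SEC23A, SEC23B, KDM1A, RCOR1, GFI1B, GATA1, KLF1 and BCL11A, the 10 genes per day with the best median rank of a gene-end peak, the 10 best-ranked genes specific to each day, and up to 4 members per list and day with the best-ranked reproducible region. Some genes that the rule takes are not reported here. Other members named by their presence alone were picked from the fixed lists after their values were seen.

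Alternatives varied the number of peaks (5000, 50000 or all), the order of ties, the window (5 kb), the overlap (50% reciprocal), the donors required (2 of 3), the peak width (200 bp at the midpoint), the gene body extension (50 kb), a score of at least 50, the pairing and the libraries, each left out in turn. Those chosen after the results were seen were autosomes alone, shifts of 50 to 500 kb, a match on gene length, the score of 50 and, over all lists, genes with no other gene end within 2 kb. For the ribosomal protein genes, this last restriction was set down before its test. The calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. They were tested on simulated lists of 20000 peaks over the 19974 genes. Of 200 genes given a gene-end peak on day 14 alone, 186 were found, and 42 other genes were called, neighbours with a shared end among them. A gene with a chance peak from the other day is left out by the rule. All 25 planted members of an enriched list were found, and of 200 tests of unrelated lists, 0 at gene ends and 2 over gene bodies had an unadjusted p below 0.05. Simulated peaks outside the planted genes were placed at random, so few unrelated genes could have a reproducible gene-end peak, unlike in the real data. These counts therefore give no rate of false calls for the real gene lists. Chromosome Y was left out. Coordinates are 1-based on GRCh38, so the start of a peak is 1 more than in the deposited list.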

Results

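LSD1 (KDM1A) is a histone demethylase that works in corepressor complexes, and its binding was mapped by CUT&RUN in erythroid cells grown from human CD34+ blood stem and progenitor cells. Cells from 3 donors were taken at day 11 and at day 14 of culture, which gave 3 LSD1 peak lists per day and 1 list per donor and day. The series set out to learn how inhibiting LSD1 raises SEC23A and corrects congenital dyserythropoietic anaemia type II, an inherited failure of red cell production caused by loss of SEC23B. SEC23A and SEC23B are paralogous subunits of COPII, the coat of vesicles that leave the endoplasmic reticulum. The labels name no treatment of the cells used for CUT&RUN, so the lists describe where peaks were called with the LSD1 antibody and not the effect of inhibiting LSD1. No IgG library was analysed and the use of a control in peak calling was not given. The peaks are therefore not shown to be specific to LSD1, and this holds for every result below.

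The 3 lists of day 11 held 342128, 174404 and 229838 peaks, and those of day 14 held 832863, 392926 and 485118, in donor order. The mean was 248790 ± 85453 at day 11 and 570302 ± 232010 at day 14 (SD, n = 3), a ratio of geometric means of 2.26 (exact permutation p = 0.1, the smallest that 3 against 3 allows). All 3 donors had more peaks at day 14 (paired exact permutation p = 0.25, the smallest possible with 3 pairs). Peaks were short, with median widths of 112 to 118 bp at day 11 and 120 to 129 bp at day 14 over all deposited peaks. Among the 20000 highest-scoring peaks of each library the median widths were 204 to 218 bp at day 11 and 339 to 426 bp at day 14. Wider peaks cover more bases, which bears on the overlaps given below. Read depths were not given, so the number of peaks may follow depth, and the comparisons that follow use the 20000 highest-scoring peaks of each library.

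At day 14, LSD1 peaks lay more often at the ends of protein-coding genes than at day 11. The share of the top 20000 peaks within 1 kb of a gene end was 18.8% ± 0.546 at day 11 and 36.7% ± 0.155 at day 14 (SD, n = 3), a difference of 17.9 percentage points. Shifted peaks gave 2.46% and 2.74%, so the enrichment over this background was 7.64 ± 0.215-fold at day 11 and 13.4 ± 0.101-fold at day 14. The peaks away from gene ends fell inside gene bodies (49.4% ± 0.979 of the top peaks at day 11 and 38.9% ± 0.318 at day 14) or between genes (31.8% ± 0.433 and 24.4% ± 0.213). All 3 libraries of day 14 lay above all 3 of day 11 in gene-end share and in enrichment (exact permutation p = 0.1 for each). The difference was 5.78 points among all peaks with a score of 50 or more. Over all peaks as deposited the shares were 6.92% ± 1.72 and 5.89% ± 1.46, a difference of -1.03 points (exact permutation p = 0.5), lower at day 14 in all 3 donors (paired -1.03 ± 0.266, SD, paired exact permutation p = 0.25, the smallest possible).

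**Figure D1:**
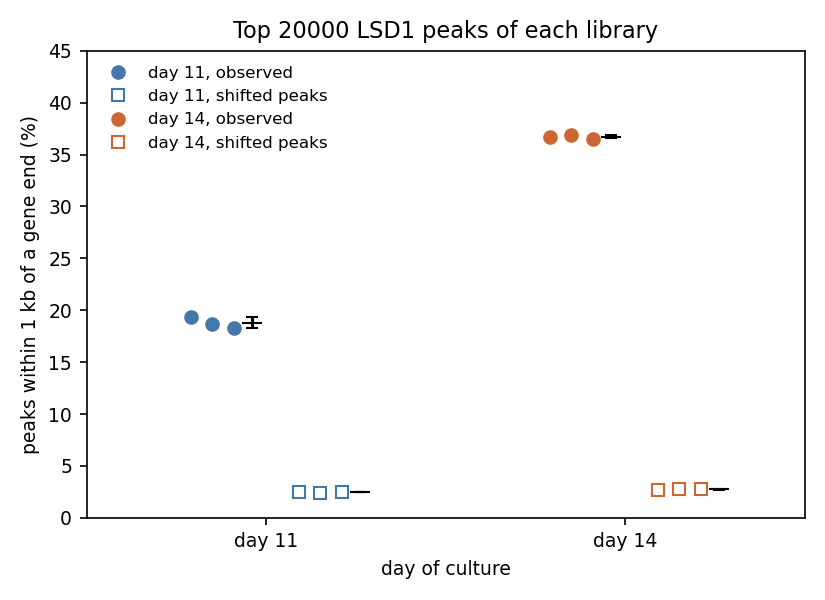
Share of the top 20000 LSD1 peaks of each library within 1 kb of an annotated end of a protein-coding gene (%), by day of culture. Filled circles are the 6 libraries, open squares are the mean of 100 circular shifts of the same peaks, and black bars are the mean and SD of 3 libraries; the libraries lie near 18.8% at day 11 and near 36.7% at day 14, with shifted peaks below 3%.

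The donors shared 5804 LSD1 regions at day 11 and 13114 at day 14, against 0.31 and 1.56 for shifted peaks. Of the regions of day 11, 4003 (69.0%) overlapped a reproducible region of day 14, and 39.4% of these shared regions lay at gene ends. The day 11 regions without such an overlap were at gene ends in 8.27% of cases, and the day 14 regions without a day 11 counterpart in 45.3%. Most regions of day 14 were not empty at day 11: 66.6% overlapped a deposited day 11 peak of any rank in all 3 donors, and 8.86% overlapped none in any donor.

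Libraries of the same day overlapped more than libraries of different days. The mean Jaccard index was 0.246 (0.239 to 0.252) among the 3 pairs of day 11, 0.489 (0.472 to 0.511) among the 3 pairs of day 14, and 0.181 between days. The difference between pairs of the same day and pairs of different days was 0.187, the largest of the 10 splits of the libraries (exact permutation p = 0.1, the smallest possible), and the highest other split gave -0.0104. With peaks reduced to 200 bp it was 0.114, with all deposited peaks 0.0305, and without 1 library it ranged from 0.118 to 0.249. Between days, libraries of the same donor had an index of 0.183 and libraries of different donors 0.180, a difference of 0.0025, the largest of the 6 permutations of donors (exact permutation p = 0.167, the smallest possible). Without day 11 replicate 1 the donor difference was -0.0069, and without day 14 replicate 3 it was -0.00298.

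**Figure D2:**
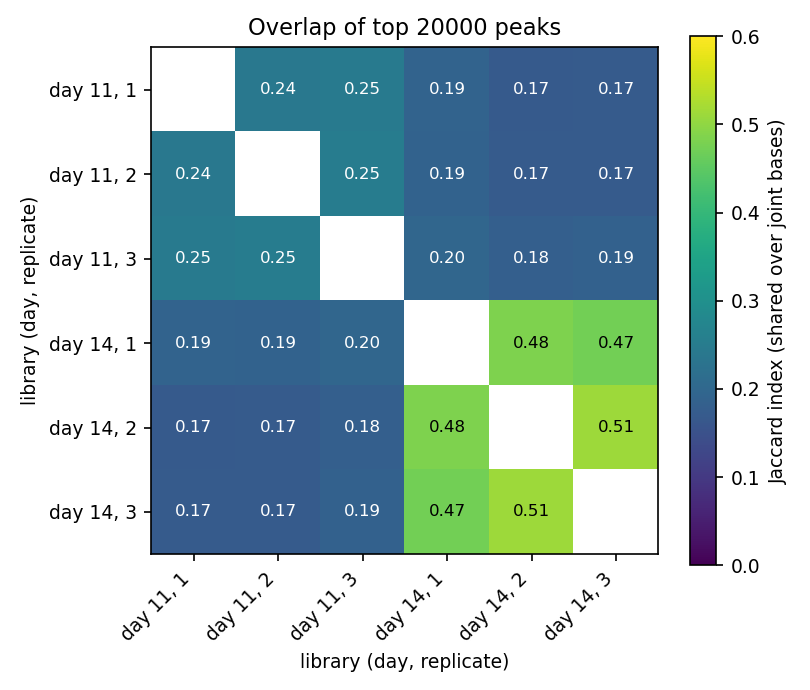
Overlap of the top 20000 LSD1 peaks between the 6 libraries, as the Jaccard index of covered bases (colour scale from 0 to 0.6, value in each cell); the diagonal is left blank. Pairs of day 14 reach 0.472 to 0.511, pairs of day 11 reach 0.239 to 0.252, and pairs of different days average 0.181.

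ERP44, a chaperone of the early secretory pathway, and INVS share the interval on chromosome 9 (ERP44 ends at 100099000 and INVS begins at 100099243) where peaks ranked 6, 8 and 10 at day 11 and 7, 6 and 4 at day 14. HSP90B1, the endoplasmic reticulum chaperone GRP94, on chromosome 12 (103930410 to 103947926) had gene-end peaks at ranks 19, 13 and 19 and then 8, 8 and 6. TMEM67, SND1 and the pair VCPIP1 and C8orf44-SGK3 were among the 10 best genes of both days. HDGF with its neighbour PRCC, MAP3K3 and HSPH1, a cytosolic chaperone, were among the best 10 at day 11, and PSMA5, a proteasome subunit, and the pair PSME3IP1 and RSPRY1 at day 14.

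A gene-end peak in all 3 donors was found at 2085 genes (10.4% of 19974) at day 11 and at 6474 (32.4%) at day 14. Of the genes of day 11, 1906 (91.4%) also had one at day 14, where independent lists would share 676. With no peak at either end in any donor of the other day required as well, 44 genes were specific to day 11 and 2273 to day 14. The genes specific to day 14 with the best ranks were TBC1D10B on chromosome 16 (ranks 192, 159 and 627), GRPEL1, a cochaperone of mitochondrial protein import, and COPE, a subunit of the COPI coat, with its neighbour DDX49. They were followed by OSBP, KMT5C, ALKBH7, YBX1, HDGFL2 and PTBP1. Those specific to day 11 were AMD1, an enzyme of polyamine synthesis (ranks 115, 360 and 3930), HMHB1, PRLHR, HSD17B7, RAB3C, RAPH1, BTN3A3, C6orf132, DNAH5 and RBBP9, the neighbour of SEC23B. No gene can pass a test of its own with 3 libraries per day. The real split gave the most genes of the 10 splits, 2317, and the highest other gave 54, so 1 split in 10 is the smallest share that can be reached. The 44 genes of day 11 became 112, 113 and 92 without day 11 replicates 1, 2 and 3, 7 with all deposited peaks and 10 at scores of 50 or more. With a library left out, a peak in the remaining donors of that day was enough. The rule was then looser, so such a rise does not show the influence of a single library. The 2273 genes of day 14 became 776 in the top 5000 peaks, 1179 with all peaks and 3653 at scores of 50 or more.

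At day 14, 3 of the erythroid lists lay above other genes at gene ends: haem and iron, red cell membrane, and maturation. Of 25 genes of haem synthesis and iron, 21 (84.0%) had a reproducible gene-end peak at day 14, against 32.3% of other genes (Fisher's exact test, adjusted p = 1.28e-06, log2 odds ratio 3.32). They included ALAS2, the erythroid enzyme that starts haem synthesis, FECH, which completes it, CPOX (ranks 263, 257 and 261), PPOX (403, 756 and 621), ALAD (4318, 5606 and 4047) and the mitochondrial iron importer SLC25A37 (946, 417 and 391). The red cell membrane and blood group list reached 23 of 31 (74.2%, Fisher's exact test, adjusted p = 1.51e-05). SLC4A1, the band 3 anion exchanger, was among them, with EPB41, protein 4.1, at ranks 7232, 12385 and 16147 and ANK1, ankyrin, at 2397, 9274 and 4301. AQP1 was at 496, 665 and 241, and SLC14A1, the Kidd urea transporter, at 2691, 598 and 735. The erythroid maturation and survival list reached 15 of 22 (68.2%, Fisher's exact test, adjusted p = 0.00391), with UBE2O, a ubiquitin ligase of maturing reticulocytes, at ranks 12, 46 and 28, BCL2L1 at 116, 70 and 153, TRIM58 at 219, 105 and 180 and CAT, catalase, at 111, 178 and 211.

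Of 81 ribosomal protein genes, 63 (77.8%) had a reproducible gene-end peak (Fisher's exact test, adjusted p = 6.64e-16), among them RPS18 (ranks 740, 609 and 498), RPS27A (448, 727 and 1100) and RPL24 (1655, 1113 and 2404). Of 18 genes of the unfolded protein and integrated stress response, 14 (77.8%) had one (Fisher's exact test, adjusted p = 0.000578), with HSP90B1, SEL1L, PDIA4 and DNAJB9 leading and EIF2AK1, the haem-regulated kinase, included. Of 9 congenital dyserythropoietic anaemia genes, 7 had one (77.8%, Fisher's exact test, adjusted p = 0.0236): SEC23B, CDIN1, KIF23, VPS4A, LPIN2, KLF1 and GATA1. Among these, SEC23B is also in the COPII list and KIF23 in the cell cycle list. KLF1 and GATA1 are also in the erythroid transcription factor list, so these lists are not independent. By Fisher's exact test, lymphoid markers (1 of 22, EBF1, adjusted p = 0.0115) and olfactory receptors (4 of 392, adjusted p = 7.67e-59) lay below the other genes.

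The remaining lists did not pass the threshold at day 14 at gene ends. By Fisher's exact test these were erythroid transcription factors (14 of 25, adjusted p = 0.0526), cell cycle and cytokinesis genes (16 of 30, 0.0526), LSD1 corepressor complexes (14 of 28, 0.141) and the COPII coat and ER export (12 of 24, 0.160). The others were mast cell, basophil and eosinophil markers (0 of 10, 0.0847 by Fisher's exact test), megakaryocyte markers (3 of 19, 0.275), stem and progenitor markers (3 of 18, 0.323), neutrophil and monocyte markers (4 of 20, 0.461) and globins (2 of 11, 0.656). At day 11, erythroid maturation and survival genes were above the other genes (7 of 22, 31.8% against 10.4%, Fisher's exact test, adjusted p = 0.0210), with UBE2O (ranks 48, 29 and 23), BCL2L1 (275, 65 and 29), TRIM58, CAT, CA1, JAK2 and RIOK3. Olfactory receptors were below (1 of 392, Fisher's exact test, adjusted p = 1.41e-16). The counts of the other lists at day 11 were 7 of 31 for the red cell membrane, 5 of 25 for haem and iron, 5 of 25 for erythroid transcription factors, 5 of 18 for the unfolded protein response and 3 of 24 for COPII. They were 3 of 28 for LSD1 complexes, 2 of 11 for globins, 1 of 9 for dyserythropoietic anaemia, 2 of 30 for the cell cycle and 6 of 81 for ribosomal proteins. Stem and progenitor (1 of 18), megakaryocyte (2 of 19), neutrophil and monocyte (0 of 20), mast cell (1 of 10) and lymphoid (0 of 22) markers completed them, and none of these passed (Fisher's exact test, adjusted p from 0.0847 to 1).

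**Figure D3:**
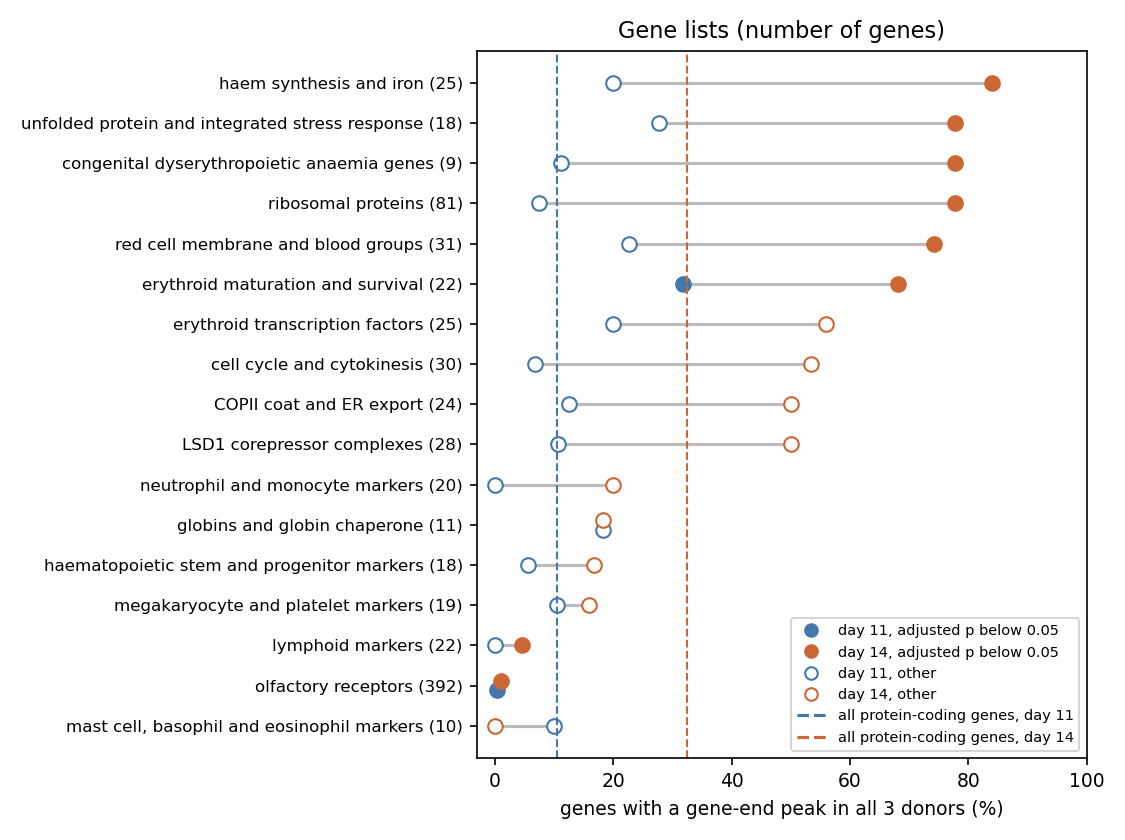
Share of each list's genes with a gene-end LSD1 peak in all 3 donors (%), at day 11 (blue) and day 14 (orange), with the number of genes in parentheses; filled points have a Benjamini-Hochberg adjusted p below 0.05 in Fisher's exact test against all other protein-coding genes, and dashed lines are the shares of all genes. Haem and iron genes reach 84.0% and ribosomal proteins 77.8% at day 14, against 32.4% of all genes.

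With 5000 peaks per library, the unfolded protein response alone lay above the other genes at day 14, and the log2 odds ratio of the red cell membrane list was -0.12 (2.53 in the top 20000). It was 1.60 for haem and iron (3.32 in the top 20000), 1.03 for ribosomal proteins (2.85) and 1.23 for maturation (2.11). The dyserythropoietic anaemia call was lost in 6 of 16 alternatives (adjusted p from 0.0164 to 1, and 0.0888 on autosomes alone). Its log2 odds ratio of 2.65 was 0.40 in the top 5000 peaks and 1.88 to 2.45 in the other 5. The day 11 call of the maturation list was lost in 6 of 16 (0.0098 to 0.131, and 0.0526 without day 11 replicate 2), and the lymphoid call in 3 of 16 (0.00251 to 0.451). Where they were lost, the log2 odds ratio was 1.21 to 2.34 for maturation (2.06 in the top 20000) and -2.59 to -0.77 for lymphoid markers (-2.78). Of the lists without a call at day 14, erythroid transcription factors passed in 11 of 16 alternatives (Fisher's exact test, lowest adjusted p = 0.00044), cell cycle genes in 8 of 16 (0.000551), LSD1 complexes in 3 of 16 (0.0098) and COPII in 2 of 16 (0.0473). Some of these passes came from leaving out day 11 replicate 1 or 3, where the day 14 peaks are unchanged. There, erythroid transcription factors kept a log2 odds ratio of 1.40 (Fisher's exact test, adjusted p = 0.0416 and 0.0456). Cell cycle genes kept 1.25 (Fisher's exact test, adjusted p = 0.0421 and 0.0456). Only the adjustment shared with day 11 moved. Below the other genes, mast cell, basophil and eosinophil markers passed in 4 of 16 (Fisher's exact test, lowest adjusted p = 0.0185). Neutrophil and monocyte markers did so in 1 of 16 (0.0476). At day 11, the red cell membrane list passed in 7 of 16 (Fisher's exact test, lowest adjusted p = 3.07e-05), haem and iron in 5 of 16 (0.000145) and erythroid transcription factors in 3 of 16 (0.000671). The unfolded protein response passed in 1 of 16 (0.0191), and lymphoid markers passed below the other genes in 1 of 16 (0.0317). In each library taken alone, the log2 odds ratio of ribosomal proteins was 0.22 ± 0.26 at day 11 and 3.10 ± 0.27 at day 14 (SD, n = 3), a difference of 2.88 (exact permutation p = 0.1, adjusted p = 0.131 over 17 lists). For haem and iron the difference was 2.27, for the unfolded protein response 2.10 and for COPII 1.21, each with the same exact permutation p of 0.1, the smallest possible. Most of the 17 lists had that p, among them olfactory receptors (-1.35), stem and progenitor markers (-1.46) and cell cycle genes (1.41). It therefore does not set the named lists apart. Erythroid transcription factors, globins, lymphoid markers and neutrophil and monocyte markers had a higher p.

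Over gene bodies with 10 kb on both sides, erythroid transcription factors stood out at both days. At day 11, 18 of 25 (72.0%) held a reproducible region, against 25.4% in random lists matched on gene length, and at day 14, 22 of 25 (88.0%) against 51.7% (permutation p = 0.0002 at both days, the smallest possible, adjusted p = 0.00085). The best-ranked were at KLF3 on chromosome 4 (38672805 to 38673484 at day 11, median rank 197), SOX6 (471), FOXO3 (610) and a region near KLF1 (628). Some of these regions lie at the end of a neighbouring gene. At day 11 the sole region counted for KLF1 lay at an end of GCDH, and the sole one counted for GATA1 lay at an end of HDAC6. The random lists were matched on gene length and not on the density of neighbouring genes. Globin genes were above matched lists at day 11 (4 of 11, permutation, adjusted p = 0.0164), as were red cell membrane genes (18 of 31, adjusted p = 0.00136) and maturation genes (12 of 22, adjusted p = 0.00371). The globin genes were HBB, HBD, HBG1 and HBG2. They are neighbours on chromosome 11, so a region within 10 kb can count for more than 1 of them. The region at 5242105 to 5242441, for example, lay within 10 kb of both HBD and HBG1. Random lists matched on gene length do not reproduce this shared counting, so the 4 genes are not independent. The best median ranks were those of GYPB (191), AQP1 (603), EPB41 (770) and SLC14A1 (853) among membrane genes, and of UBE2O (29), BCL2L1 (65), XPO7 (563) and TRIM58 (811) among maturation genes. GYPB and the gamma-globin genes have near-identical paralogs, so their peaks are uncertain.

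At day 14, regions lay in all 25 haem and iron genes, 28 of 31 red cell membrane genes, 21 of 22 maturation genes and 68 of 81 ribosomal protein genes, each above matched lists (permutation, adjusted p = 0.00085), and in 16 of 18 genes of the unfolded protein response (adjusted p = 0.00136). Olfactory receptors were below matched lists at both days (7 and 15 of 392, permutation, adjusted p = 0.00085). No other list passed. By permutation these included COPII (6 of 24 at day 11 and 17 of 24 at day 14, adjusted p = 1 and 0.287), LSD1 complexes (8 and 21 of 28, 1 and 0.0961) and globins at day 14 (5 of 11, 0.287). They also included haem and iron at day 11 (10 of 25, 0.0969), dyserythropoietic anaemia genes (3 and 8 of 9, 0.873 and 0.0845) and cell cycle genes (8 and 21 of 30, 0.780 and 0.0845), with ribosomal proteins (16 of 81, 0.231) and the unfolded protein response (7 of 18, 0.191) at day 11. Stem and progenitor markers (6 and 6 of 18), megakaryocyte markers (5 and 8 of 19), neutrophil and monocyte markers (3 and 8 of 20), mast cell markers (3 and 2 of 10) and lymphoid markers (5 and 9 of 22) had adjusted p from 0.287 to 1. The globin call at day 11 was lost in 4 of 14 alternatives (adjusted p from 0.00397 to 0.162), among them the lists without day 11 replicate 3 (0.0521). The maturation call at day 11 was lost in the top 5000 peaks (17.9 points above matched lists, 32.9 in the top 20000, adjusted p = 0.0841 by permutation). At day 14, the red cell membrane call was lost in the top 5000 peaks (14.1 points above matched lists, 37.2 in the top 20000, adjusted p = 0.230 by permutation) and the maturation call with all peaks (18.3 points, 44.3 in the top 20000, 0.101). Without a call in the top 20000, cell cycle genes passed at day 14 in 7 of 14 alternatives, globins at day 14 in 6 of 14 and haem and iron at day 11 in 6 of 14. Ribosomal proteins passed at day 11 in 3 of 14 (permutation, lowest adjusted p = 0.0068). LSD1 complexes at day 14 and the unfolded protein response at day 11 passed in 1 of 14 each. COPII passed at day 14 in 4 of 14 (permutation, lowest adjusted p = 0.0136), and without day 14 replicate 3 it lay 29.5 points above matched lists, against 15.8 with all libraries.

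Among lists without a call, the best-ranked regions are given by median rank. A region within 10 kb of a gene can belong to a neighbour. Of COPII genes, TMED10, a cargo receptor, had 1124 at day 11 and 664 at day 14, and SURF4, another, had 1380 and 671. TRAPPC3 (1547) and SEC24D (2740) followed at day 11 and TMED2 (1500) and SEC31A (1844) at day 14. Of LSD1 complex genes, MBD2 (172 and 375) and GATAD2B (591 and 124), both of the NuRD remodelling complex, led, and GSE1 had 1365 and 1148. HMG20B had 1229 at day 14. Of cell cycle genes, CDK6 (236), E2F1 (413) and CDK2 (470) led at day 11, and CDK2 (43), CENPA (248), CDK4 (858) and CDKN2D (1175) at day 14. Stem and progenitor markers with regions included MECOM (2307), MEIS1 (4040) and ERG (4971) at day 11 and MLLT3 (3979), CRHBP (4092) and HMGA2 (8762) at day 14.

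CEBPE, a granulocyte factor, had a region in its flank with median rank 173 at day 11 and 117 at day 14. It was followed by LYZ (4942) and CSF1R (7770) at day 11 and CSF1R (1000), CD68 (2180) and IRF8 (3516) at day 14. Of megakaryocyte markers, GP9 had 1703 and 1119, NBEAL2 4868 and 834 and ITGA2B 6842 and 4306. GP1BA (4646) came next at day 14. ENPP3 had 445 and 7863 and PRG2 12226 and 7197 among mast cell, basophil and eosinophil markers, with HDC (4151) at day 11. Of lymphoid markers, RAG2 had 1626 and 4547 and EBF1 5985 and 3384, with TCF7 (8210) at day 11 and CD79A (3034) at day 14. The region counted for LCK (2641 and 1528) is the gene-end peak of its neighbour HDAC1. Other regions named here can also lie away from the gene's own ends. CEBPE, IRF8, GP9, RAG2 and CD79A, among others, had no reproducible gene-end peak on either day. The few olfactory receptors with regions were led by OR51B5 and OR51B6 (699), beside the beta-globin cluster, at day 11 and by OR2V1 (3142) at day 14.

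The SEC23A locus was examined because the series asked how LSD1 bears on this gene. SEC23A lies on chromosome 14 (39031919 to 39103235), and no library of either day had a top 20000 peak within 1 kb of its ends. Deposited peaks of lower rank lay there in all 6 libraries, at ranks 25230, 48056 and 137499 at day 11 and 93062, 46768 and 457436 at day 14. A reproducible region lay 11014 bp beyond its upper end at day 11 (39114112 to 39114388, median rank 2718) and 11060 bp beyond it at day 14 (39114046 to 39114545, median rank 3130), within 1 kb of an end of GEMIN2 and of the uncharacterised LOC105370459. It was the sole reproducible region of either day within 50 kb of SEC23A. Inside the gene, 1 top peak was found in 1 library (day 11 replicate 1, 39085068 to 39085268, rank 18133).

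SEC23B, on chromosome 20 (18507548 to 18561415), had a reproducible region over its lower end at day 14 (18507358 to 18508055, ranks 6469, 7690 and 3959). At day 11 the gene-end peaks of SEC23B ranked 40952, 38346 and 223355, below the top 20000. Nearby, a region between DZANK1 and POLR3F was reproducible on both days (18466992 to 18467408 at day 11 and 18466954 to 18467451 at day 14). Other nearby regions were 1 at RBBP9 at day 11 (18496896 to 18497391), 1 away from gene ends at day 11 (18596768 to 18597036) and 1 at SMIM26 at day 14 (18567167 to 18567616). Deposited peaks at the same gene end in all 3 donors are common, at 34.0% of genes at day 11 and 60.6% at day 14, so having such peaks does not set SEC23A apart from other genes. These shares lie above those of 20 shifts of the peaks (0.585% and 5.35%), so such peaks are not explained by position at random. By the median rank of the best gene-end peak, 29.1% of genes stood ahead of SEC23A at day 11 and 55.6% at day 14. For SEC23B the percentages were 26.2% and 19.1%. They are not comparable between days, because more genes had deposited gene-end peaks at day 14. At day 11, RCOR1, which lacked such a peak in most donors, had just 57.0% of genes ahead of it.

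**Figure D4:**
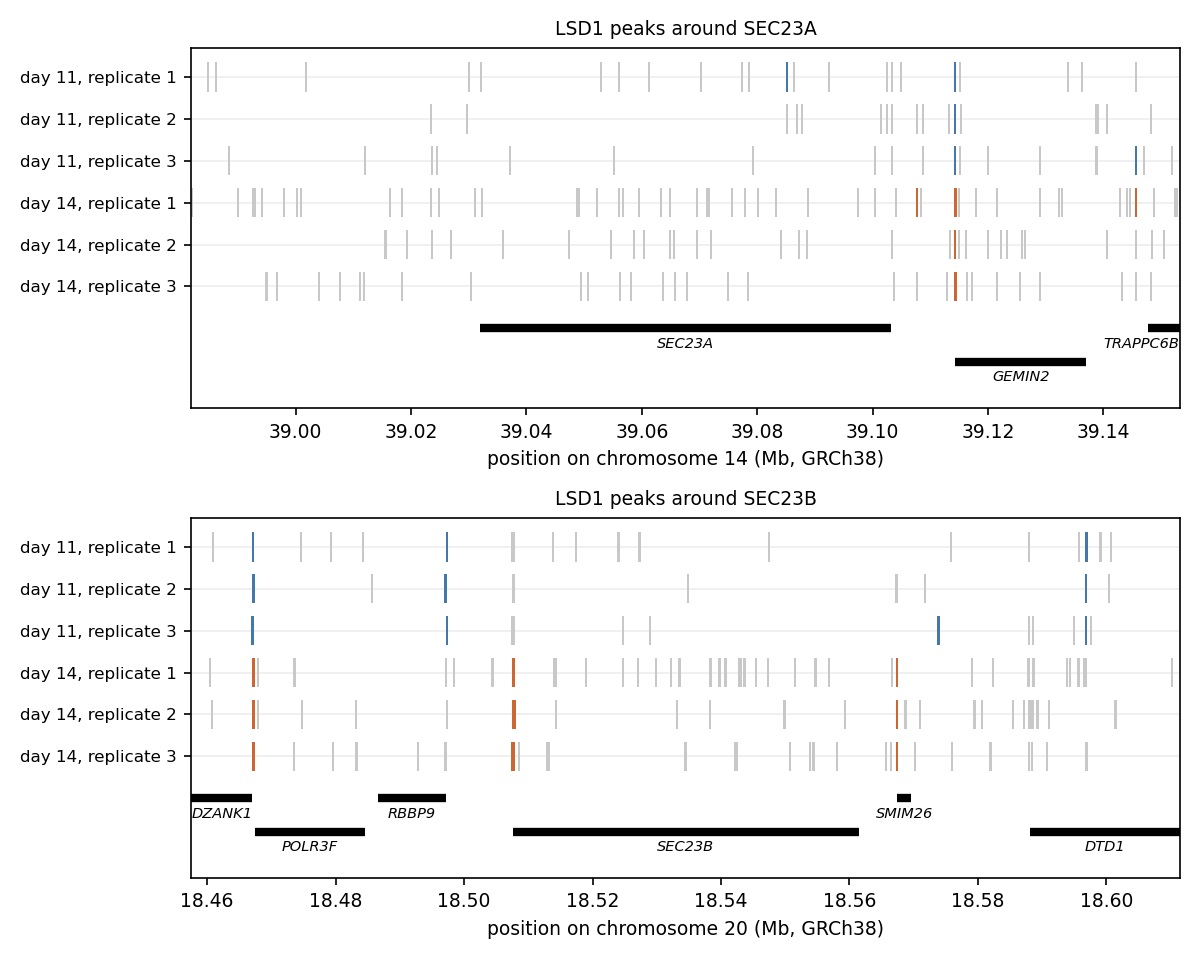
LSD1 peaks of the 6 libraries around SEC23A (chromosome 14) and SEC23B (chromosome 20) with 50 kb on each side, positions in Mb on GRCh38; coloured bars are top 20000 peaks (blue day 11, orange day 14), grey bars are lower-ranked deposited peaks, with the shortest drawn wider than they are, and black bars are protein-coding genes. The SEC23A ends carry grey bars alone, the region beside GEMIN2 is coloured in all 6 libraries, and the lower end of SEC23B is coloured in the 3 libraries of day 14.

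Regions at LSD1's own complex and its erythroid partners are given beside the totals of 5804 regions at day 11 and 13114 at day 14, and the LSD1 complex list passed on neither day. KDM1A itself had a region at its lower end at day 14 alone (chromosome 1, 23019241 to 23019671, ranks 8598, 3226 and 9145). RCOR1, its corepressor partner, had no reproducible region within 50 kb at day 11 and 2 at day 14. GFI1B, a repressor that recruits LSD1, had an intragenic region on both days (chromosome 9, 132978502 to 132978850 at day 11, median rank 1999, and 132978376 to 132979191 at day 14, median rank 1314). GATA1, the master erythroid regulator on chromosome X, had a region at its lower end at day 14 (48785748 to 48787114). At day 11 it had a top peak at a gene end in 2 of 3 libraries. KLF1, on chromosome 19, had regions at both ends at day 14 (12883696 to 12884438 and 12887110 to 12887905), and a region beside it at GCDH was reproducible on both days. BCL11A, a repressor of fetal globin genes on chromosome 2, had intragenic regions at 60473556 to 60473857 and 60498146 to 60498592 at day 11 and at 60490533 to 60491233, 60494813 to 60495946 and 60497466 to 60498829, among others, at day 14. HBB, the beta-globin gene on chromosome 11, had a region at its upper end on both days (5227042 to 5227324 and 5226802 to 5227446).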

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

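The test of the top 5000 peaks, the length match of the ribosomal protein genes and the count of peaks in mitochondrial pseudogenes were chosen after the results were seen. The other tests were set down before. The top 5000 peaks were an alternative fixed in advance, but their use to weigh an explanation came later. The restriction to genes with no other gene end within 2 kb was set down before for ribosomal protein genes, and its use over all lists came later.

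Gene-end peaks took a larger share of the top 20000 at day 14 than at day 11, by 17.9 percentage points. If background specific to each donor were the whole cause, regions shared by all 3 donors would have similar shares at the 2 days. They differed by 13.8 points (29.8% against 43.5%), and every pair of donors at day 11 (25.6% to 27.6%) lay below every pair at day 14 (41.1% to 41.6%). The test cannot decide about background that recurs in all 3 donors, because such background passes the filter and no control library was analysed. A partial contribution of donor-specific background also stays open. A deeper reach of the ranked lists at day 11 stays open: the difference was 22.99 points in the top 5000 peaks (29.9% against 52.9%), but an equal number of peaks leaves an unequal reach in place, and it was 5.78 points at scores of 50 or more. The difference of 13.9 points within 250 bp of a gene end (12.5% against 26.4%) decides nothing about peak width, since midpoints were counted throughout. Read depth, peak calling against a control and maturation of the cells were not tested and stay open.

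Ribosomal protein genes had a gene-end peak in 6 of 81 cases at day 11, near the 10.5% of other genes, and in 63 of 81 at day 14. Their shortness is argued against as the whole cause, since random lists matched on gene length held such peaks in 26.3% of genes against 77.8% (permutation p = 0.000200, the smallest possible). Peaks of neighbouring genes are also argued against: with no end of another protein-coding gene within 2 kb, 36 of 44 (81.8%) had a peak against 25.2% of other genes, an odds ratio of 13.4 (Fisher's exact p = 5.72e-15). The CpG content of their promoters was not tested and stays open, as does a biological difference between the days.

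The mitochondrial genome, which is outside the nuclear comparisons and has no control library analysed here, held the highest-scoring peak of every list, with 9, 8 and 5 peaks in the libraries of day 11 and 11, 9 and 11 in those of day 14, over 15.2 to 16.1 kb. Its best score was 872815 to 1031891 at day 11 and 107422 to 183152 at day 14, while the lowest score of the top 20000 peaks was 44 to 49 and 81 to 114. Scores are not comparable between lists of unknown read depth, so no difference between the days is drawn from these values. In all 6 libraries the 3 highest-scoring nuclear peaks lay in or within 1 kb of mitochondrial pseudogenes, on chromosome 1 within 633971 to 634097 (beside MTATP6P1) and 629907 to 630010 (beside MTND2P28) and on chromosome 17 within 22521370 to 22521551 (MTCYBP13). Reads shared between mitochondrial DNA and its nuclear copies stay open as a source: the count of 3 of 3 in every library was the observation that prompted the test and decides nothing. Whether LSD1 binds there was not tested.

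For the number of genes specific to a day, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 2317, and the highest other split gave 54; 10 splits are too few for a share under 0.05. The same held for the 4 splits that exchange days within donors.

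The log2 odds ratio of mast cell, basophil and eosinophil markers at gene ends differed between the days by -3.42 over 10 genes (exact permutation p = 0.1), but at day 11 2 of 10 had a peak in every library, against 20.5%, 19.7% and 19.4% of other genes, so no opposite direction was shown in every library. Peaks on unplaced and unlocalised contigs, which no comparison used, numbered 234, 58 and 110 at day 11 and 705, 247 and 316 at day 14. Transfer RNA genes, also outside the comparisons, had a gene-end peak in all 3 donors in 7 of 443 cases at day 11 and in 100 of 443 at day 14, and among the 333 that lie away from ends of protein-coding genes in 2 and 42.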

How the results depend on the processing

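Values among all peaks that scored 50 or more, on autosomes alone, with shifts of 50 to 500 kb, with lists matched on gene length and among genes with no other gene's end within 2 kb were chosen after the results were seen. The last of these restrictions was set down before its test for the ribosomal protein genes, and its use over all lists came later. The other alternatives, the top 5000 peaks among them, were fixed before the data were examined. The use of the top 5000 peaks to weigh an explanation came later. The read depth was not given, and 6 lists of peaks with 3 donors per day cannot give an exact p below 0.1 between days (0.25 with donors paired), so no p of this kind speaks to stability. The motif comparisons and the match on CpG content were not run, because no genome sequence was used here.

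The excess of peaks at gene ends at day 14 depended on the length of the ranked lists. The day difference was 22.99 percentage points in the top 5000 peaks, 10.3 in the top 50000 and 5.78 among all peaks scoring 50 or more. It was -1.03 points (exact permutation p = 0.5) among all peaks as deposited, where the difference in enrichment over shifted peaks was -0.463 (exact permutation p = 0.4); the cause was not tested. The enrichment at day 11 and day 14 was 11.9 and 18.8 with the top 5000 peaks, 5.32 and 8.82 with the top 50000, 2.81 and 2.35 with all peaks, 3.02 and 4.52 with a 5 kb window, 8.15 and 9.74 at scores of 50 or more, and 5.18 and 7.93 with shifts of 50 to 500 kb. On autosomes alone it was 13.2 at day 14. With donors paired (the replicate block), the mean ratio of peaks (2.26), the differences in gene-end share (17.9 points) and enrichment (5.76), and the difference in overlap (0.187) keep their values by construction. Neither exact test can reach the threshold with these libraries, so pairing could change no call.

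Regions called in all 3 donors at day 11 and day 14 numbered 1816 and 3355 with the top 5000 peaks, 10329 and 23098 with the top 50000, and 24924 and 46364 with all peaks. With 2 of 3 donors required there were 13184 at day 11 and 18456 at day 14, and at scores of 50 or more there were 5250 and 21007. The difference in overlap between pairs of the same and of different days was 0.114 with peaks reduced to 200 bp, 0.0305 with all peaks, and 0.118 to 0.249 with each library left out in turn. Genes with a gene-end peak on day 14 alone numbered 776 in the top 5000, 1179 with all peaks and 3653 at scores of 50 or more. Those on day 11 alone numbered 7 with all peaks, 10 at scores of 50 or more and 112 with a 5 kb window.

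The number of gene lists above other genes at gene ends was 0 at day 11 and 1 at day 14 with the top 5000 peaks, where 1 list lay below at day 14. At day 11 it was 2 with the top 50000 peaks and 2 with all peaks (2 lists below), 4 with a 5 kb window, 3 with 2 of 3 donors, 0 with lists matched on gene length, and 2 among genes without a close neighbour, where 1 list lay below at day 14. Over gene bodies, 2 lists lay above at day 11 with the top 5000 peaks. Of the 328 alternatives to the 22 list values past the threshold, 302 stayed past it in the same direction, 25 fell short of it and 1 changed direction. Of the 692 alternatives to the other 46 list values, 74 passed the threshold and 70 changed sign, none of them past the threshold. Both totals include alternatives that left out a library of the other day, where the list's own peaks are unchanged. There, only the adjustment over both days or the draw of random lists could move a p. Such alternatives therefore do not speak to stability.

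Leaving out each library in turn gave 0 to 4 lists above other genes at gene ends at day 11, and 55 to 113 genes with a gene-end peak on day 11 alone. A library left out also lowered the number of donors that a call required, so these counts can change through the looser rule. The difference in overlap between same-donor and other-donor pairs ranged from -0.0069 to 0.00807. It was below 0 without day 11 replicate 1 (-0.0069) and without day 14 replicate 3 (-0.00298). Leave-one-out ranges that crossed 0 for lists, as log2 odds ratios at gene ends at day 11, were -0.82 to 1.10 for stem and progenitor markers, -0.080 to 0.29 for megakaryocyte markers, -0.13 to 0.63 for LSD1 complex genes, -0.76 to 0.12 for ribosomal proteins and -0.77 to 0.17 for cell cycle genes. Over gene bodies, as percentage points above length-matched lists, they were -4.04 to 5.04 for lymphoid markers, -7.7 to 1.58 for COPII genes and -2.52 to 1.71 for LSD1 complex genes at day 11, and -5.96 to 3.27 for neutrophil and monocyte markers at day 14.

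The other changes of sign, with untested cause, follow as log2 odds ratios at gene ends and as percentage points over gene bodies. With the top 5000 peaks, the ratio at day 14 was -0.12 for red cell membrane genes, which lay above other genes in the top 20000, and 0.98 for globin genes. At day 11 it was -0.15 for globin genes, 0.078 for cell cycle genes, 0.83 for stem and progenitor markers, -0.91 for megakaryocyte markers and -0.017 for mast cell markers. Over gene bodies at day 11 the difference was 1.62 for COPII genes, -5.59 for stem and progenitor markers and -2.75 for megakaryocyte markers. With the top 50000 peaks at day 11, the ratio was -0.13 for dyserythropoietic anaemia genes, 0.22 for stem and progenitor markers and -0.44 for megakaryocyte markers, and the gene body difference was 4.75 for COPII genes, 1.05 for neutrophil and monocyte markers and -3.52 for lymphoid markers.

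With all peaks, the ratio at day 11 was -0.32 for globin genes, 0.58 for cell cycle genes, 0.96 for stem and progenitor markers, -1.28 for megakaryocyte markers, -0.81 for mast cell markers and 0.35 for ribosomal proteins, and at day 14 it was 2.19 for globin genes. The gene body difference at day 11 was 5.65 for COPII genes, -1.97 for LSD1 complex genes, -4.24 for megakaryocyte markers, 11.7 for neutrophil and monocyte markers and -1.78 for lymphoid markers. At day 14 it was 0.453 for stem and progenitor markers and 5.83 for neutrophil and monocyte markers. With another order of tied peaks, the ratio for cell cycle genes at day 11 was 0.13. With a 5 kb window at day 11 it was -0.047 for LSD1 complex genes, 0.48 for cell cycle genes, 0.076 for neutrophil and monocyte markers and -0.26 for mast cell markers. With 2 of 3 donors at day 11 it was 0.91 for stem and progenitor markers, -0.61 for megakaryocyte markers and 0.10 for ribosomal proteins, and the gene body difference was -2.21 for LSD1 complex genes and 3.66 for neutrophil and monocyte markers at day 14.

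With gene bodies extended by 50 kb, the difference at day 11 was 16.9 for COPII genes, -1.25 for stem and progenitor markers, -2.68 for megakaryocyte markers and 7.20 for neutrophil and monocyte markers, and at day 14 it was 6.57 for neutrophil and monocyte markers and 11.1 for lymphoid markers. At scores of 50 or more, the ratio for mast cell markers at day 11 was -1.16, and the gene body difference was 0.788 for COPII genes and -0.814 for LSD1 complex genes at day 11 and 1.28 for stem and progenitor markers at day 14. On autosomes alone, the ratio for cell cycle genes was 0.15 and the gene body difference for dyserythropoietic anaemia genes -1.12, both at day 11. Matched on gene length, the ratio was -0.00081 for COPII genes, -0.18 for LSD1 complex genes and 0.12 for ribosomal proteins at day 11, and 0.40 for globin genes at day 14. Among genes without a close neighbour at day 11 it was -0.35 for dyserythropoietic anaemia genes and 0.18 for stem and progenitor markers.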

Other observations

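The families and gene types described here were chosen after the results were seen.

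Several gene families outside the fixed lists had many LSD1 peaks at gene ends at day 14. Reproducible gene-end peaks were found at 35 of 50 proteasome subunits, 38 of 55 translation initiation factors, 31 of 46 subunits of respiratory complex I, 50 of 77 mitochondrial ribosomal proteins and 47 of 79 histone genes, against about 32.3% of other genes (Fisher's exact test, adjusted p over 28 tests from 5.06e-08 to 5.42e-06). At day 11 the same families had 11, 8, 4, 13 and 3, of which the proteasome subunits lay above the other genes (Fisher's exact test, adjusted p = 0.0345). BTB zinc finger genes (22 of 42, adjusted p = 0.0198), autophagy genes (11 of 18, 0.0347) and zinc finger genes at large (193 of 517, 0.0345) were also above the others at day 14 (Fisher's exact test). Below the other genes at day 14 were HOX genes (0 of 40), keratins (0 of 55) and protocadherins (1 of 65; adjusted p = 9.05e-07, 8.39e-09 and 8.39e-09, Fisher's exact test), and the same counts lay below at day 11 (0.0347, 0.00989 and 0.0302). By Fisher's exact test, solute carriers were below the others (98 of 386, adjusted p = 0.00925), and tubulins (7 of 27, 0.608) and ubiquitin conjugases (16 of 36, 0.214) did not pass.

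Among other types of gene, reproducible gene-end peaks were found at 599 of 18176 long non-coding RNA genes at day 11 and 1714 at day 14, and at 4 and 22 of 154 small nuclear RNA genes. Away from the ends of protein-coding genes, these counts were 150 and 337 of 12707 and 3 and 15 of 134. Pseudogenes had 56 and 133 of 15212. The highest-ranked nuclear region away from the ends of protein-coding genes, apart from those in mitochondrial pseudogenes, was the same on both days, on chromosome 2 near KIF1A (240832334 to 240832621 at day 11, 11074 bp from its nearest end, median rank 4, and 240832247 to 240832728 at day 14, median rank 5).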
